A study of Caenorhabditis elegans with 4 samples.

How the data were processed

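H3K36me3, histone H3 trimethylated at lysine 36, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans worms of the standard laboratory strain N2 at the L3 larval stage. Per the labels' protocols, ground frozen worms were crosslinked for 10 minutes in 1% formaldehyde and the chromatin was sonicated. Libraries were made from DNA fragments of 250 to 500 bp with 18 cycles of PCR. The series has 4 samples, which are 2 immunoprecipitations with the same Abcam antibody, numbered 1 and 7 in the labels, and 2 input DNA samples. The labels name a different input sample as the control of each immunoprecipitation.

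Each immunoprecipitation has 1 deposited peak list, called on that sample alone, so that the replicates were not pooled. Coordinates are in WormBase WS190 per the file headers, and the names of the peaks carry the name of the peak caller MACS. The source column of the same files reads MA2C, the name of another program, so the files do not settle which program made the peaks and scores. BWA, a read aligner, is named in the submitters' processing notes. The versions and settings of BWA and of the peak caller are not given in the sources used here. Each peak has a start, an end and a score that the authors deposited. The headers do not say what the score is, so it was used mainly to rank or filter peaks within a list. The 1 use across lists was a correlation of the scores of matched peaks. Its Pearson's r takes the raw scores, tied values included. The score is exactly 3100 for 945 peaks of replicate 1 and 790 of replicate 7. Ties among the highest scores were broken by width in choosing the regions named below. Settings that kept the top-scoring peaks broke ties by chromosome and start. The lists hold no read counts, so the sequencing depth is unknown, and no signal between peaks could be measured. The input samples entered only through the authors' peak calling, and no values of the inputs were analysed here.

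The 2 lists were compared by overlap with a minimum of 1 bp. Chance overlap was set by 1000 random rotations of one list along each chromosome, which keep peak widths, gaps and numbers per chromosome. The smallest p that these one-sided permutation tests can give is 0.001. The covered share is the percentage of a chromosome or region that lies under peaks. Chromosome lengths were taken as the last peak end in either list, because no WS190 genome was used here, and they sum to 100.1 Mb. The centre of a chromosome is its middle 50% and the arms are the rest. Per-sample values are given with the SD over the 2 replicates. The labels do not say whether the replicates came from separate cultures, so the SD measures only the spread between these 2 samples, which may be technical. Shares of peaks have exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent.

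The tests across chromosomes were an exact permutation test and exact sign tests. Intervals from resampling windows of about 500 kb 2000 times, within the arms and the centre of each chromosome, were added after the data had been examined, as were the comparison of individual arms between replicates, the centre over arm ratio of the X, its contrast with the autosomes, the other differences between replicates in cover, and the settings that held each list to 10 or 15 Mb of its top-scoring peaks, or to 6 Mb of covered autosome centre. Leaving out each autosome in turn, limiting the score comparison to pairs below 3100, and filling gaps of replicate 7 inside a replicate 1 peak were also added then, as was the number of peaks per Mb in arms and centres, with each peak placed by its midpoint. The window intervals describe unevenness along the genome within a library and not the spread between cultures. These alternatives were set before the data were examined, for the comparisons planned then: overlap by 50% of a peak, reciprocal 50% overlap, the upper 50% of peaks by score, equal numbers of peaks, joining of peaks within 500 bp, autosomes alone, peaks per Mb for the ratio of X to autosomes, and the centre as the middle 40%.

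The regions named were chosen by a rule set before the data were examined. For each list the rule takes the 3 highest-scoring peaks that overlap the other list, the 3 highest-scoring peaks that do not, and the 3 widest peaks. Peak-free stretches and the windows with the highest and lowest cover were chosen after their values were seen. The 4 planned comparisons that need gene positions were not run. They concern exons against introns, the position along genes, genes marked in both replicates, and 28 fixed gene lists. The gene table used for names is on assembly WBcel235, and coordinates of different builds were not mixed. Genes under the peaks are therefore not named.

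Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The overlap code was tested on simulated data before use. It matched a base-by-base count with 0 differing peaks. For the comparison of replicate 1 with replicate 7, a simulated pair of lists of 4022 peaks with 70% of peaks shared gave 69.9%, and 1 of 20 unrelated pairs passed the rotation test at 0.05. Simulated peaks were spaced so that unshared ones could not overlap. In the real lists, rotation gave a mean overlap of 32.1% for replicate 1 peaks. The unrelated pairs were made by rotating 1 list, as the test itself does. These runs therefore check the code and not the accuracy of the share or the test on real lists.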

Results

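H3K36me3 is a histone mark of transcribed gene bodies. It was profiled by ChIP-seq in whole N2 worms at the L3 larval stage, in 2 immunoprecipitated samples (replicates 1 and 7) that were each called against their own input DNA. Replicate 1 had 5973 peaks and replicate 7 had 6223. The peaks covered 18.3 Mb and 17.4 Mb, a mean of 17.9% ± 0.620 (SD, n = 2) of the 100.1 Mb spanned by the lists. The median peak width was 2313 bp in replicate 1, with an interquartile range of 1435 to 3865 bp, and 2134 bp in replicate 7, with a range of 1372 to 3438 bp. Peaks wider than 10 kb numbered 132 and 97, and held 9.44% and 6.88% of the covered length. The depth of the libraries is unknown from the peak lists.

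The first comparison asked how far the replicates marked the same regions. Of the replicate 1 peaks, 89.6% (5351 peaks, 95% interval 88.8 to 90.4%) overlapped a replicate 7 peak. Of the replicate 7 peaks, 94.8% (5901 peaks, 94.2 to 95.4%) overlapped a replicate 1 peak. The rotated lists gave a mean of 32.1% and at most 41.7% for the former share, and a mean of 32.4% and at most 43.3% for the latter. Both overlaps exceeded all 1000 rotations (one-sided permutation test, p = 0.001, the smallest it can give). The replicates shared 16.14 Mb of covered sequence, which was 82.2% of the 19.6 Mb covered in either, against a mean of 11.6% and a maximum of 18.4% over the rotations (permutation p = 0.001).

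The domains were cut into peaks somewhat differently. A total of 670 replicate 1 peaks overlapped 2 or more replicate 7 peaks, whereas 300 replicate 7 peaks overlapped 2 or more replicate 1 peaks. Where 1 peak matched 1 peak (4189 pairs), the median ratio of widths, replicate 7 over replicate 1, was 1.00. Across these pairs the authors' scores correlated with a Spearman's rho of 0.91 and a Pearson's r of 0.92, and neighbouring peaks are not independent replicates. Across 998 windows of 100 kb, the covered length of the replicates correlated with a Pearson's r of 0.98 and a Spearman's rho of 0.98.

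Peaks present in 1 list alone tended to be narrow and low-scoring. The 622 peaks found in replicate 1 alone had a median width of 1067 bp and a median score of 90.8, against a median width of 2527 bp for its shared peaks and a median score of 815 over the whole list. The 322 found in replicate 7 alone had a median width of 1215 bp and a median score of 90.5. Its shared peaks had a median width of 2221 bp, and the whole list had a median score of 624. Some peaks of 1 list alone scored above the median of their list, up to 976 in replicate 1 and 1573 in replicate 7. In the lowest 20% of scores, 56.8% (95% interval 53.96 to 59.7%) of replicate 1 peaks and 78.9% (76.5 to 81.1%) of replicate 7 peaks overlapped the other list. In the highest 20% all 1195 replicate 1 peaks and all 1245 replicate 7 peaks did. From the lowest to the highest class the median width rose from 1076 to 5505 bp in replicate 1. In replicate 7 it rose from 1106 to 4873 bp, so the classes do not separate score from width. Peaks of 1 list alone made up 4.08% of the covered length of replicate 1 and 2.60% of that of replicate 7.

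**Figure D1:**
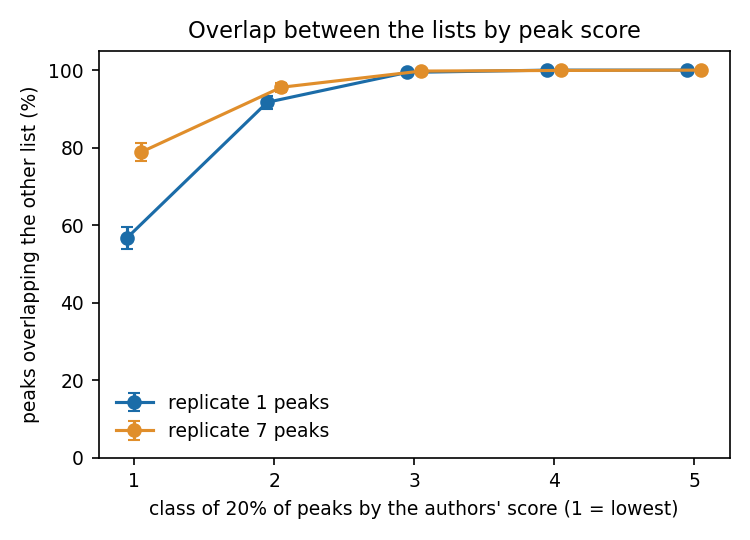
Percentage of peaks that overlap the other list by at least 1 bp (vertical axis) in classes that each hold 20% of a list by the authors' score (horizontal axis, 1 = lowest), for replicate 1 (blue) and replicate 7 (orange); bars are exact 95% binomial intervals. The lowest class stands at 56.8% in replicate 1 and 78.9% in replicate 7, and the 3 highest classes lie above 99%.

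The highest-scoring shared regions lay on several autosomes (WS190 coordinates). In replicate 1 they were chromosome III 7730980 to 7736732, chromosome I 3581382 to 3585908 and chromosome III 5375527 to 5379827, each with the score 3233.06. In replicate 7 they were chromosome I 12567810 to 12571060, chromosome II 3079928 to 3086150 and chromosome I 2071073 to 2075945, with scores of 3233.06, 3227.04 and 3223.52. Of the peaks scoring 3100 or more (1013 in replicate 1 and 842 in replicate 7), 945 and 790 had exactly 3100. The score looks saturated there, and the order of peaks from that value up may carry no meaning. The widest peak of replicate 1 was a domain of 30.3 kb on chromosome I (4602989 to 4633286), over which replicate 7 had 6 separate peaks. It was followed by 25.2 kb on chromosome IV (4360676 to 4385836) and 24.5 kb on chromosome I (4334521 to 4359057). The last of these was also the widest in replicate 7, at 24.7 kb (chromosome I 4334381 to 4359049), ahead of 21.7 kb on chromosome III (5380648 to 5402343) and 19.6 kb on chromosome II (10248546 to 10268190).

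Of all peaks without a partner, 37.9% (236 of 622) in replicate 1 and 30.4% (98 of 322) in replicate 7 lay within 1000 bp of a peak of the other list, with median distances of 1600.5 and 2710.5 bp. The median gap between peaks was 2808.5 bp in replicate 1 and 2568 bp in replicate 7. A peak without a partner lies in a gap of the other list, and no chance level is given for these distances. The 3 highest-scoring peaks without a partner in replicate 1 were chromosome III 3183005 to 3185145, chromosome I 1383324 to 1387054 and chromosome I 11573597 to 11577275, at 2378, 3339 and 1089 bp from the nearest replicate 7 peak. The 3 of replicate 7 were chromosome II 12002764 to 12004638 and chromosome IV 11333112 to 11336921, at 690 and 153 bp from a replicate 1 peak, and chromosome III 732185 to 736009, at 36513 bp.

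The second comparison set the X chromosome against the autosomes. In C. elegans the X is subject to dosage compensation and is largely silent in the germ line. H3K36me3 peaks covered 9.15% ± 0.0370 (SD, n = 2) of the X, the lowest share of the 6 chromosomes, and 19.7% ± 0.760 of the autosomes together. The share was 0.464 ± 0.0198 of that of the autosomes, at 0.450 in replicate 1 and 0.478 in replicate 7. Chromosomes III (27.9% ± 1.27) and I (27.8% ± 1.30) had the highest cover, followed by chromosome II (20.1% ± 0.526) and chromosome IV (16.6% ± 0.601). Chromosome V, which carries many chemoreceptor genes, was the autosome nearest to the X, at 10.9% ± 0.339.

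The X was the lowest of the 6 chromosomes in both replicates (exact permutation over chromosomes, one-sided p = 0.167, the smallest that 6 chromosomes allow). Resampling of windows gave 95% intervals of the ratio of 0.398 to 0.504 in replicate 1 and 0.423 to 0.534 in replicate 7. The X had 35.5 and 33.98 peaks per Mb in replicates 1 and 7, against 64.8 and 68.2 on the autosomes. The median width of X peaks was 2108.5 bp in replicate 1, below the 2346 bp of autosomal peaks, and 2233 bp in replicate 7, above the 2127 bp of autosomal peaks. The median X peak had a score at the 43.4th percentile of its list in replicate 1 and the 48.9th in replicate 7. The share of replicate 1 peaks that overlapped replicate 7 was 91.9% on the X and 89.3% on the autosomes. The reverse share was 94.5% and 94.9%.

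**Figure D2:**
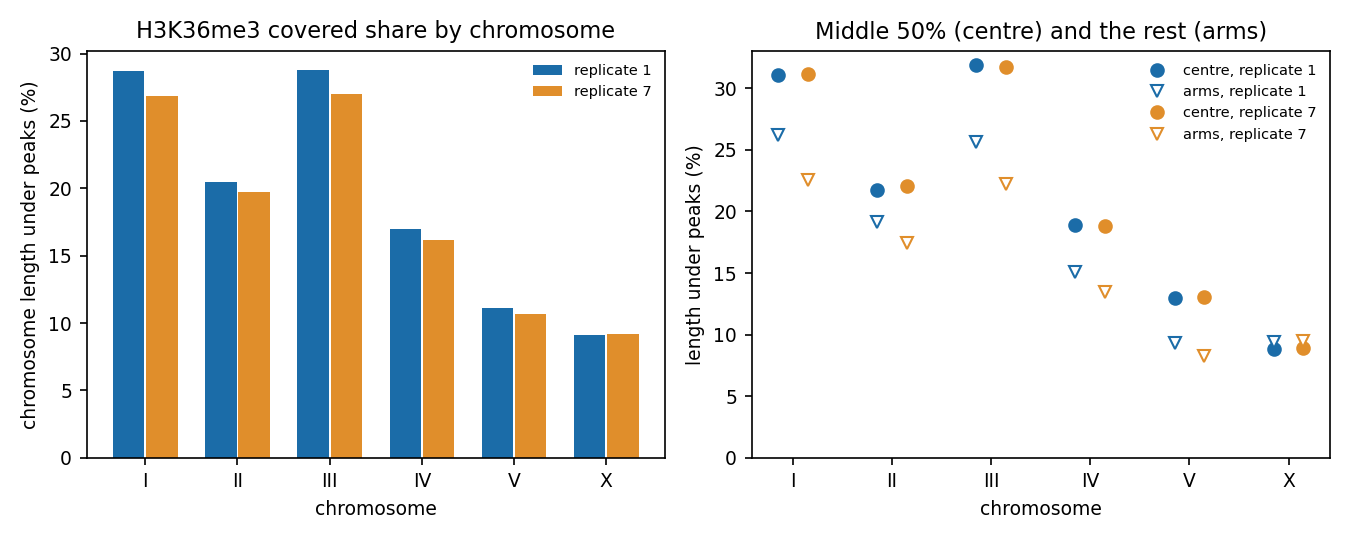
Left, percentage of each chromosome under H3K36me3 peaks (vertical axis) for replicate 1 (blue bars) and replicate 7 (orange bars). Right, the same for the middle 50% (filled circles) and the rest (open triangles) of each chromosome. The X is lowest at 9.12% and 9.17%, and the arms of each autosome lie lower in replicate 7 than in replicate 1.

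The third comparison set chromosome centres against arms, which in this worm differ in gene content, conserved and essential genes being concentrated in autosome centres. Autosome centres had 22.3% of their length under peaks in replicate 1 and 22.4% in replicate 7. Autosome arms had 18.2% and 16.01%. The ratio of centre to arm was 1.31 ± 0.119 (SD, n = 2), at 1.23 in replicate 1 and 1.396 in replicate 7, with window intervals of 1.10 to 1.37 and 1.26 to 1.57. Centres exceeded arms on 5 of 5 autosomes in both replicates (exact sign test, two-sided p = 0.0625, the smallest that 5 chromosomes allow).

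The ratio was highest on chromosome V (1.48 ± 0.127) and lowest among autosomes on chromosome II (1.2 ± 0.0914). The X had 8.86% ± 0.0228 of its centre and 9.43% ± 0.0511 of its arms under peaks. Its ratio of 0.94 in both replicates had window intervals of 0.774 to 1.15 and 0.763 to 1.15, which include 1, and was 1.09 and 1.10 with the top-scoring 10 Mb of each list. The difference between autosomes and X in the log2 of this ratio was 0.38 (0.05 to 0.72) in replicate 1 and 0.57 (0.23 to 0.92) in replicate 7. With the top-scoring 10 Mb the interval of replicate 1 included 0, at 0.48 (-0.06 to 1.02).

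On chromosome II the left arm had 12.4% ± 0.863 of its length under peaks and the right arm 24.2% ± 1.61, above the centre at 21.9% ± 0.187. On chromosome IV the left arm had 18.6% ± 1.79, close to the centre at 18.8% ± 0.0611. This arm was above the centre in replicate 1 (19.9% against 18.9%) and below it in replicate 7 (17.4% against 18.8%). The right arm of chromosome IV, which carries a large cluster of piRNA genes, had 9.95% ± 0.490. The arms of chromosome V had 9.32% and 8.30% of their length under peaks in replicates 1 and 7, against 9.39% and 9.47% in the arms of the X.

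The replicates differed in the autosome arms. Cover was lower in replicate 7 in 10 of 10 autosome arms (exact sign test, two-sided p = 0.00195), at 0.819 to 0.952 of the replicate 1 value. This compares 2 libraries, and arms are not replicates. In the 5 autosome centres the ratio was 0.995 to 1.01, with 2 of 5 lower in replicate 7 (exact sign test, p = 1). The difference, replicate 7 minus replicate 1, was -2.17 percentage points in the arms (window interval -2.61 to -1.75) and 0.0244 in the centres (-0.126 to 0.177). With each list held to its top-scoring 10 Mb it was -1.76 in the arms and 1.27 in the centres (0.825 to 1.71). The arm difference in cover ranged from -2.76 to -1.35 over the alternatives, which were chosen after seeing the data. In number of peaks it went the other way, with 2613 peaks in the arms in replicate 1 and 2899 in replicate 7, against 2734 and 2725 in the centres. The arms had 63.4 and 70.3 peaks per Mb, a difference of 6.94 (4.49 to 9.19), and the median width of arm peaks was 2030 bp in replicate 1 and 1627 bp in replicate 7. In percentage points the left arm of chromosome I moved most, from 27.9% to 22.9%, followed by the left arm of chromosome III, from 22.3% to 18.4%. The X arms were at 9.39% and 9.47%. Of replicate 1 peaks in autosome arms, 14.5% (95% interval 13.2 to 15.9%) had no partner in replicate 7, against 7.02% (6.09 to 8.05%) in autosome centres and 8.15% (6.13 to 10.6%) on the X. The shares of replicate 7 peaks without a partner were 5.80%, 4.44% and 5.51%. Within bins of 10% of the peaks by score, arms minus centres was 1.89 percentage points in replicate 1 and -2.02 in replicate 7.

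**Figure D3:**
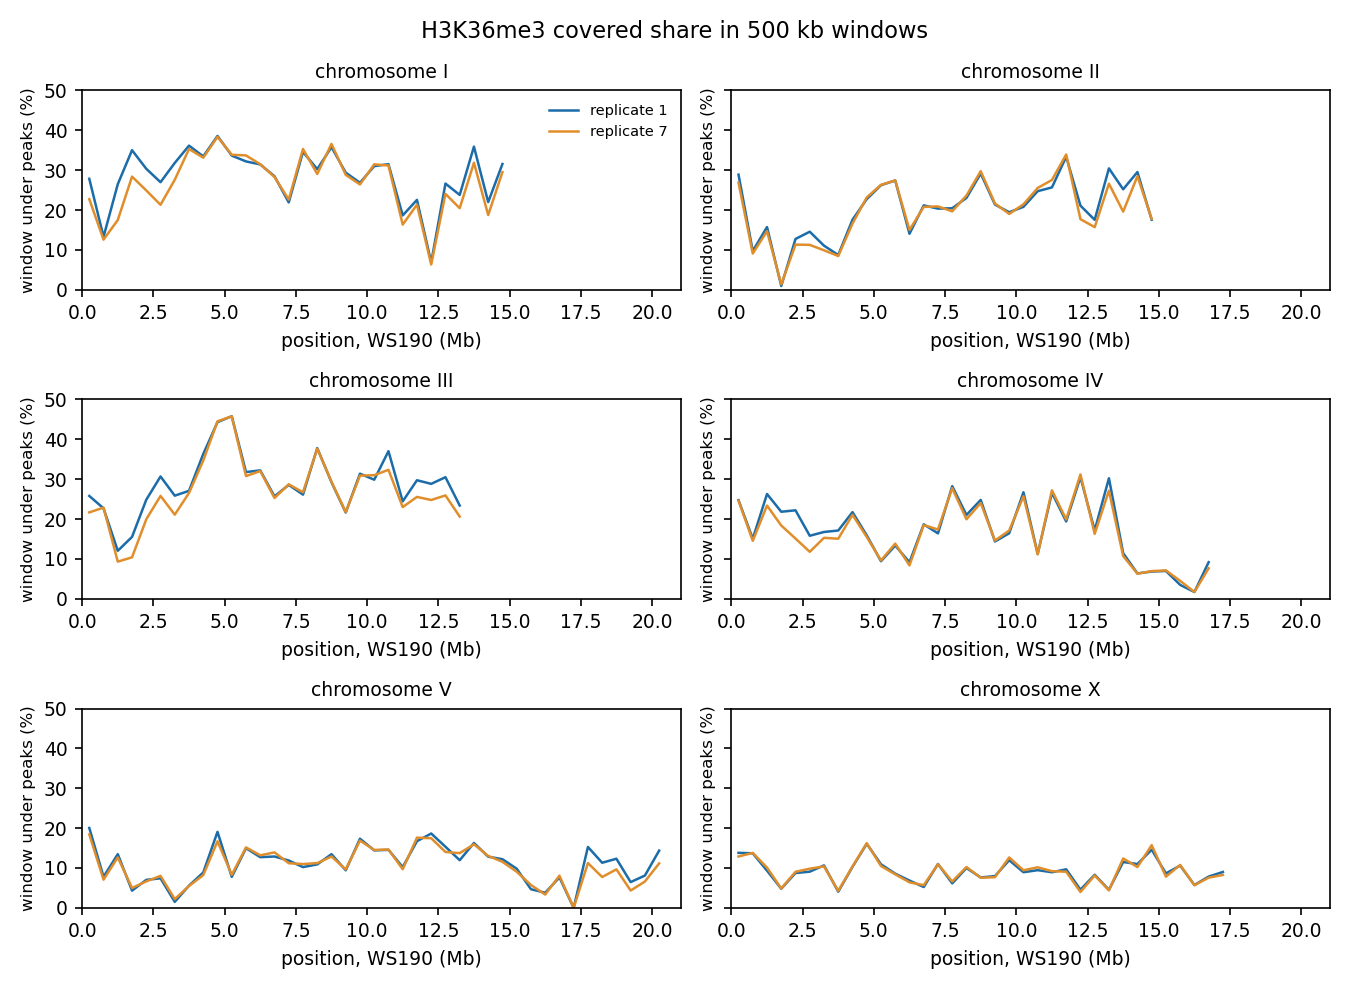
Percentage of each full 500 kb window under H3K36me3 peaks (vertical axis) along the 6 chromosomes (horizontal axis, WS190 position in Mb), for replicate 1 (blue) and replicate 7 (orange). The lines nearly coincide over autosome centres and the X, replicate 1 lies above replicate 7 over many arm windows, and cover ranges from 0 on chromosome V (17 to 17.5 Mb) to 45.8% on chromosome III (5 to 5.5 Mb).

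Along the chromosomes, the 500 kb windows with the highest cover lay in the left part of the chromosome III centre. They spanned 5 to 5.5 Mb (45.8% ± 0.0276, SD, n = 2) and 4.5 to 5 Mb (44.4% ± 0.145), ahead of chromosome I 4.5 to 5 Mb (38.5% ± 0.168). The window of chromosome V from 17 to 17.5 Mb had no base under a peak in either replicate. It lay inside the longest stretch free of peaks in both lists, 547 kb on the right arm of chromosome V (16967901 to 17515122). The next were 385 kb (3759211 to 4144107) and 381 kb (18114838 to 18495651) on the same chromosome, and 271 kb on chromosome IV (4812290 to 5083274). Of the 15 stretches over 200 kb without a peak in either list, 8 lay on chromosome V, 4 on chromosome IV, 1 each on chromosomes I, II and X, and 0 on chromosome III. A stretch without peaks shows that no enrichment passed the authors' threshold, not that the mark is absent.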

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

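Both overlap shares and the shared covered length exceeded every rotation under every alternative run (permutation p = 0.001), with 78.3 to 90.4% of replicate 1 peaks, 75.1 to 95.7% of replicate 7 peaks and 67.95 to 83.0% of covered length shared; the lowest of these came from reciprocal 50% overlap for the peaks and from the top-scoring 10 Mb for the length. The settings at 10 and 15 Mb, the autosomes left out in turn, the pairs below 3100 and all alternatives for the differences between replicates were chosen after seeing the data. The correlation of scores fell to a rho of 0.86 among pairs below 3100 in both lists. The X remained below the autosomes throughout, at a mean ratio of 0.41 with the upper 50% of peaks by score, 0.355 with the top-scoring 10 Mb, 0.439 with 15 Mb and 0.52 in peaks per Mb. Without chromosome I, III or V the ratio was 0.511, 0.506 or 0.403. Leaving out each replicate gave 0.450 to 0.478. The centre over arm ratio was 1.63 with the upper 50% of peaks, 1.78 with 10 Mb and 1.50 with 15 Mb, and 1.23 to 1.396 when each replicate was left out. The cause of these shifts was not tested. The higher X ratio of replicate 7 reversed in peaks per Mb, where the difference was -0.0494, and was larger with the upper 50% of peaks (0.0809), 15 Mb (0.0685) and 10 Mb (0.110). The arm difference between replicates kept its sign in each setting that measured cover, at -2.76 to -1.35 percentage points, and reversed in number of peaks, where replicate 7 had 6.94 more peaks per Mb of arm. Joining peaks within 500 bp moved neither ratio by more than the SD between replicates. Leaving out chromosome II or IV moved the X ratio by less than its SD, and so did the middle 40% as centre for the centre over arm ratio. The ratio of centre to arm on the X lay between 0.92 and 1.10 over the alternatives. The difference between autosomes and X in this ratio kept its direction, and its interval included 0 for replicate 1 with 10 Mb. The alternatives that need gene positions were not run. No paired analysis was possible because the inputs have no values here and both immunoprecipitations belong to 1 group. The lists hold no counts, so regions weaker than the authors' threshold cannot be compared.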

Other observations

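The tests in this part were chosen after the results were seen. The outcomes predicted for 3 of them were written before their values were seen: arms and centres within bins of 10% of the peaks by score, the filling of gaps in replicate 7, and the ratio of the X to autosome centres with those centres held to 6 Mb. No outcome was written beforehand for the arm difference at 6 Mb.

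The X had a smaller share of windows without peaks than chromosomes IV and V, although its total cover was lower. Of 176 windows of 100 kb on the X, 5 (2.84%) had no base under a peak in either replicate, against 28 of 209 (13.4%) on chromosome V and 13 of 174 (7.47%) on chromosome IV. The shares on chromosomes I, II and III were 0.667%, 1.32% and 2.19%. No window of the X or of chromosome IV was covered by at least 50% in both replicates. Such windows numbered 6 on chromosome I, 6 on chromosome III, 1 on chromosome II and 1 on chromosome V. Peaks over 10 kb numbered 5 on the X (17.6 Mb) in each replicate, and 7 and 6 on chromosome V (20.9 Mb) in replicates 1 and 7. The autosomes together had 127 and 92.

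Autosome arms were covered less in replicate 7 than in replicate 1, with a difference of -2.17 percentage points over the full lists, while the difference was 0.0244 in autosome centres and 0.0523 on the X. The arms nevertheless had more peaks in replicate 7, by 6.94 per Mb (4.49 to 9.19), and by 4.1 (2.33 to 5.75) after joining peaks within 500 bp. The lowest score was 50.11 in replicate 1 and 50.05 in replicate 7, which argues against a lower score cutoff in the replicate 1 list. The same score may not mean the same stringency in both lists. A replicate 1 list that reaches further down the same order of peaks is argued against as the whole cause. The arm difference was -1.76 (window interval -2.38 to -1.20) with each list held to its top-scoring 10 Mb. With centres held to 6 Mb in each list it was -2.76 (-3.39 to -2.1). Centres differed by 1.27 (0.825 to 1.71) at 10 Mb, where the fixed total makes a loss in arms appear as a gain elsewhere. Each list was ranked by its own scores, so other differences in calling or depth that shift arm scores cannot be excluded. Gaps left inside broad domains are argued against as the whole cause, since filling all 859 gaps of replicate 7 that lay inside a single replicate 1 peak left -1.6 (-1.97 to -1.23). The excess of partnerless peaks in arms over centres was 7.48 percentage points in replicate 1 and 1.89 (0.490 to 3.2) within bins of score. In replicate 7 it was 1.35 and -2.02 (-3.16 to -0.832). Nearness to the threshold may account for part of the excess in replicate 1. Whether it accounts for all of that excess stays open. The bins use a list's own score, whereas a peak lacks a partner by the threshold of the other list. The replicates shared 0 input libraries, so a difference between inputs cannot be told apart from one between the immunoprecipitations, and no biological explanation was tested.

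The ratio of X to autosomes was higher in replicate 7 than in replicate 1 by 0.0279 (window interval 0.0183 to 0.0380) in covered share, by 0.0809 with the upper 50% of peaks, by 0.0685 with the top-scoring 15 Mb and by 0.110 (0.0784 to 0.144) with the top-scoring 10 Mb. In peaks per Mb it was lower, with a difference of -0.0494. Over the full lists this may follow from the arms alone, since the ratio of the X to autosome centres differed by 0.0019 (-0.00525 to 0.00906). Among top-scoring peaks, with centres held to 6 Mb in each list so that arms do not enter, the ratio of the X to autosome centres was 0.261 in replicate 1 and 0.299 in replicate 7, a difference of 0.0383 (0.0142 to 0.0639), so there the arms do not account for all of it. The cause of that part stays open, with the inputs again among the candidates.

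The narrowest peak was 553 bp in replicate 1 and 762 bp in replicate 7. Of 47 replicate 1 peaks under 762 bp, 29 were found in replicate 1 alone, out of 622 such peaks.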
